A study of Xenopus laevis with 2 samples.

How the data were processed

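RNA was measured in 2 libraries of Xenopus laevis animal caps, the ectodermal roof of the early embryo, taken from embryos that had been injected with RNA for xnr2 (nodal2), a Nodal ligand of the TGF-beta family. Per the labels' protocols and the series' design text, RNA was injected into early cleavage embryos, caps were cut at stage 10 and harvested at stage 14, and 10 explants were pooled for each RNA extraction. Libraries were made from polyA-selected RNA with an Illumina TruSeq kit that does not mark strand, and single-end reads of either of a pair of lengths were sequenced. Which length belongs to which library is not given in the sources used here. The labels number the libraries 1 and 3 and put both in 1 group. Nothing in the labels says that they came from separate clutches, so the spread between them may be biological or technical.

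Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR 2.4.0k and processed with HOMER and edgeR. Per the file headers, exon reads were counted per gene model without regard to length by HOMER, on Mayball gene models placed on assembly version 9.1 of the X. laevis genome, and then rescaled with HOMER's simple normalization. The handling of reads that map to several places is not given in the sources used here. The deposited signal is therefore an exon read count per model multiplied by 1 constant per library, rounded to 2 decimals, and both columns sum to the same total (20900445.86 and 20900432.14). The other deposited numbers used are each model's exon length and its position. The header's commands name 4 libraries, of which the other 2 carry a name with wt and 6 h. Values for those 2 libraries and a comparison with them were not analysed here. No column of another sample was used (0 such columns).

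Whole reads were recovered from the deposited signal. In each library the low values are multiples of what 1 read is worth, 0.808 in library 1 and 0.715 in library 3. Dividing by this step gave whole numbers, within 0.05, for 100% of nonzero values in both libraries. The recovered counts sum to 25880104 exon reads in library 1 and 29238297 in library 3. These are 69.5% and 68.0% of the 37256829 and 42978772 aligned tags that the header states. Levels are given in CPM, on the total of recovered exon reads of each library. With 1 group, no count test between groups could be fitted, so edgeR served only for TMM factors and for the dispersion between the libraries, and DESeq2 only for size factors. A count of 0 allows a level of up to 3 reads, 0.116 CPM in library 1 and 0.103 CPM in library 3. Binomial intervals and this floor cover counting error only, since the reads carry no molecular identifiers.

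The table holds 24364 gene models, of which 519 carry no gene symbol and took a mean of 1.32% of the reads. The models are named after human genes (13465 symbols), so that the L and S copies of a gene, and Xenopus paralogs such as the nodal genes, share a symbol. A model is identified here by its symbol and chromosome on version 9.1. Reads of near-identical copies may have been split between models or lost.

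The plan written before the data were examined was built around a deposited comparison with control caps. It fixed 21 gene lists, the rule for naming genes and the alternatives. As no comparison was analysed here, and as the unit was a scaled signal, the planned counts of higher and lower genes, the enrichment of lists among them, the list medians of fold changes and the agreement of fold changes between L and S copies could not be computed. In their place, levels, the difference between the libraries and the ratio of L to S copies are reported. The list levels, the library differences and the L to S ratio, with their settings (pseudocount, read minimum, matching), were chosen after the table and first list medians had been seen. The correlation of the libraries and the number of models at 1 CPM had been fixed before, as had a minimum of 10 reads per copy as an alternative for pairs. The parts of the naming rule that rest on fold changes and p-values could not be applied either. Genes are named instead as the 4 members of a list with the highest mean CPM, the 10 highest models of the table, and, between libraries, the 10 models each way with the largest log2 ratio among those at a mean of 10 CPM or more. Every other gene named was chosen after its values were seen, which holds for all genes named as low or absent and for the examples of list differences between the libraries.

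A list's level is the median over its models of the mean CPM, set beside the medians of 10000 random lists of the same size from all named models. A list's difference between libraries is the median log2 ratio of library 3 over library 1, log2((CPM + 0.1)/(CPM + 0.1)), over models with at least 10 reads in both libraries together. It is set beside 10000 random lists matched on level in 10 bins and, as an alternative, on level and exon length in 5 bins. Lists of genes that are expressed together vary more between samples than random lists do, so a percentile describes these 2 libraries and is no test of a condition. Single models were compared between the libraries with a 2-sided exact binomial test of their reads, with Benjamini-Hochberg adjustment over the 18820 models with 10 reads. That test compares these 2 libraries only. L and S copies were paired where exactly 1 model of a symbol lay on the L chromosome and exactly 1 on the S chromosome of the same number, and their CPM were divided by exon length. Correlations across genes treat genes as the units, which are not independent replicates.

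The methods were tested on simulated data. Scaling whole numbers by a constant and rounding lost no read count in 24364 models (100% recovered). In counts drawn for the 18820 models with counting error only, the binomial test found 68% of 1.5-fold, 78% of 2-fold, 94% of 4-fold and 100% of 8-fold changes. It called 0.0215% of unchanged models. No other variation between libraries was simulated, so these rates do not carry over to the real libraries. For the list check, ratios were drawn independently for each gene, without a trend in level or length. A shift of 0.5 in lists of 60 genes was recovered as 0.50 ± 0.070 (SD over 60 lists), and 3.33% of unchanged lists lay outside the central 95%. Analyses used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, DESeq2 1.42.0). Alternatives changed the scaling, the pseudocount, the read minimum, the matching, the treatment of copies, the division by length and the libraries included.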

Results

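Animal caps injected with xnr2 RNA were profiled at stage 14, the neural plate stage, in 2 libraries of 10 pooled explants each. Left alone, animal cap tissue forms epidermis, and Nodal signals are known to turn it into mesoderm and endoderm. The question asked here was which genes such caps express. Library 1 held 25880104 exon reads and library 3 held 29238297. Of 24364 gene models, 15310 reached 1 CPM in both libraries and 2257 had no read in either. All values below are means of the 2 libraries with their SD (n = 2), and no control caps enter any statement, so that a level is not a response to xnr2.

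The most abundant transcripts included those of a translation factor, a heat shock cognate and a skeletal muscle light chain. Whether any function was enriched among them was not tested. The translation elongation factor EEF1A1 stood first at 15453 ± 1205 CPM for its model on chromosome 5S and 6209 ± 345 CPM for its model on Scaffold28. The heat shock cognate HSPA8 followed at 8468 ± 833 CPM (7S) and 7332 ± 1042 CPM (7L), and the RNA-binding protein CIRBP at 8234 ± 213 CPM (1L) and 7264 ± 1285 CPM (1S). The nucleolar protein NCL reached 6389 ± 683 CPM on Scaffold44, TPT1 reached 4777 ± 377 CPM (2L), and the mitochondrial ADP/ATP carrier SLC25A5 reached 3813 ± 580 CPM (8L). The tenth model was the skeletal muscle light chain MYL1 at 3733 ± 665 CPM (9_10L).

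Paraxial mesoderm and skeletal muscle genes formed the highest tissue list. Of 97 models of 42 matched members, 80 reached 1 CPM in both libraries, and together they took 5.03 ± 0.125% of all exon reads. Their median was 102.8 CPM, above the median of all 10000 random lists. Besides MYL1, the leading models were the muscle creatine kinase CKM at 3362 ± 703 CPM (chromosome 8L, 49657469 to 49666838), the cardiac actin ACTC1 at 3073 ± 670 CPM (8L, 89545703 to 89552165) and the fast light chain MYLPF at 2953 ± 301 CPM (9_10S). The myogenic factor MYOD1 reached 580 ± 169 CPM from its S copy (4S, 22733979 to 22736264) and 289 ± 79.2 CPM from its L copy. Its relative MYF5 reached 108 ± 42.7 CPM (3L). MYOD1 and MYF5 were picked after their values were seen.

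Posterior genes were also high. In the list of posterior genes and Hox, 57 of 70 models reached 1 CPM in both libraries, and the median of 14.5 CPM was exceeded by 25 of 10000 random lists. The caudal-type factors led it, with CDX4 at 359 ± 6.02 CPM (8S) and 324 ± 57.6 CPM (8L) and CDX2 at 218 ± 15.8 CPM (3S) and 169 ± 0.967 CPM (2L). The presomitic mesoderm factor MSGN1 reached 144 ± 9.73 CPM (5L), and HOXB8 reached 93.5 ± 33.6 CPM (9_10L). Both were picked after their values were seen.

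Axial mesoderm transcripts were present at intermediate levels. In the notochord list 24 of 32 models reached 1 CPM in both libraries, with a median of 11.01 CPM that lay above 9180 of 10000 random lists. The leading models were the collagen lysyl hydroxylases PLOD2 at 986 ± 352 CPM (5L) and PLOD1 at 241 ± 91.7 CPM (7L) and 149 ± 30.0 CPM (7S), and the BMP antagonist chordin, CHRD, at 362 ± 129 CPM (5S). Brachyury, given as T, reached 83.6 ± 35.2 CPM (5L) and 49.9 ± 22.2 CPM (5S). The dorsal mesoderm and organizer list, which shares CHRD and T, had 27 of 47 models at 1 CPM and a median of 2.67 CPM, above 1686 of the random lists. CHRD was followed there by the secreted protein TSKU at 137 ± 29.9 CPM (2L) and 114 ± 33.3 CPM (2S) and by T. The early organizer factor goosecoid, GSC, picked after its values were seen, had 14 and 0 reads in libraries 1 and 3 for its L copy and 12 and 1 for its S copy.

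Of the genes of the Nodal pathway, 30 of 50 models reached 1 CPM in both libraries, with a median of 8.29 CPM. GDF3, a TGF-beta ligand, led with 230 ± 82.3 CPM on Scaffold21, ahead of the Nodal antagonist DAND5 at 146 ± 19.0 CPM on Scaffold20, SMAD4 at 57.2 ± 9.21 CPM (1L) and the corepressor DRAP1 at 50.1 ± 11.6 CPM (4L). The deposited names give all Nodal paralogs 1 symbol, so the injected gene could not be read off by name. Of 10 models called NODAL, 3 exceeded 10 CPM. They lay at 125414360 to 125416891 on 3L (48.1 ± 7.63 CPM), at 125408255 to 125412894 on 3L (20.8 ± 8.94 CPM) and at 20870517 to 20873218 on 3S (16.6 ± 1.06 CPM). Reads from injected RNA and from the embryo's own gene are not separated in such counts. The Nodal antagonists LEFTY2 (5L) and CER1 (1S) reached 5.31 ± 2.26 and 7.81 ± 2.41 CPM, while the L model of CER1 had 0 reads.

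Endoderm genes were mostly low. Only 19 of 56 models reached 1 CPM in both libraries, and the median of 0.174 CPM lay below that of all 10000 random lists. The highest models were the protease inhibitor A2M at 920 ± 39.2 CPM (7S), CDX2, and a model called FOXA1 at 57.9 ± 5.71 CPM (4L). Other models called FOXA1 had 38.2 ± 0.826 CPM (8S), 38.1 ± 1.97 CPM (4S) and 29.6 ± 3.69 CPM (8L). The symbol does not tell which Xenopus gene each of them is. GATA6 reached 15.7 ± 0.380 CPM (6L), and both models of HHEX, a factor of the anterior endoderm, had 0 reads in either library. SOX17, an endoderm factor whose spelling in the table did not match the list, reached 78.9 ± 19.0 CPM (6S) and 62.2 ± 3.42 CPM (6L) and was looked up after the list had been read. In the list of ventral and lateral mesoderm, blood, heart and kidney, 27 of 62 models reached 1 CPM and the median was 0.712 CPM, above 8 of 10000 random lists. Its leading models were LMO2 at 366 ± 8.38 CPM (4S), the apelin receptor APLNR at 255 ± 16.7 CPM (1S) and 185 ± 4.73 CPM (1L), and WNT8A at 60.6 ± 2.09 CPM (3S). The blood factor GATA1 had 0 reads for both copies in both libraries.

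Among lists of ectoderm, epidermis held 57 of 124 models at 1 CPM in both libraries and 0.515 ± 0.0267% of reads, with a median of 1.80 CPM that lay above 59 of 10000 random lists. With the models of a symbol added up, the epidermis median instead stood at the 86.4 percentile of random lists. The low rank thus held for single models and not for symbols. A symbol can pool paralogs as well as L and S copies, so neither rank describes single genes. The highest models were the simple epithelial keratins KRT8 at 1145 ± 143 CPM (2L) and 797 ± 186 CPM (2S) and KRT18 at 735 ± 23.2 CPM (2L) and 716 ± 115 CPM (2S). Levels of regulators in the list ranged widely: MSX1 reached 52.8 ± 11.7 CPM (1L), MSX2 42.0 ± 0.896 CPM (3S) and GATA2 20.4 ± 10.6 CPM (4S), and the highest models of TFAP2A and TP63 reached 1.77 ± 0.717 CPM (6L) and 1.61 ± 0.528 CPM (5L). In the neural plate list 61 of 151 models reached 1 CPM, and its median of 0.730 CPM lay below that of all random lists. It was led by the Notch ligand DLL1 at 545 ± 152 CPM (8L) and 272 ± 0.700 CPM (5S), SALL1 at 335 ± 22.2 CPM (4L) and the tubulin TUBB2B at 274 ± 20.8 CPM (8L). Other models called TUBB2B had 238 ± 1.22 CPM (Scaffold20), 11.5 ± 0.246 CPM (3L), 7.37 ± 0.366 CPM (6L) and less. The symbol does not tell which Xenopus tubulin each of them is. The neural adhesion molecule NCAM1 reached 7.83 ± 1.84 CPM (7S), and PAX6 stayed at or below 1.08 ± 0.170 CPM (7L) in all its models. Neural crest genes had a median of 5.13 CPM and 34 of 47 models at 1 CPM, led by MYC at 231 ± 62.4 CPM (6L) and 183 ± 9.45 CPM (6S), SOX5 at 178 ± 54.8 CPM (3S) and SNAI2 at 147 ± 17.7 CPM (9_10L). The SNAI2 models on 9_10S, 6L and 6S had 125 ± 15.4, 5.80 ± 0.372 and 4.44 ± 1.90 CPM. The shared symbol does not tell which Xenopus gene each of them is. Other members of the list differed widely. FOXD3 reached 50.5 ± 13.1 CPM (4L) and SOX8 45.1 ± 8.82 CPM (9_10L), while SOX10 had 0 reads for both copies in both libraries. TFAP2A, also in this list, was low as given above.

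The multiciliated cell list had 51 of 80 models at 1 CPM and a median of 4.68 CPM, close to the middle of the random lists (4843 of 10000 lower). TUBA1A led it at 144 ± 89.2 CPM (9_10S), followed by RSPH1 at 47.0 ± 1.85 CPM (2L), WDR16 at 35.1 ± 21.4 CPM (9_10L) and the dynein chain DNAI1 at 28.5 ± 6.68 CPM (1L). The regulators MCIDAS and FOXJ1 were low, with at most 2 reads per library for MCIDAS and 4.43 ± 1.43 CPM for the highest FOXJ1 model (9_10S). The list of ionocytes and small secretory cells had 21 of 57 models at 1 CPM and a median of 0.309 CPM, above 1 random list. Its leading symbols were FOXA1, shared by models on 4L, 4S, 8L and 8S, and then DMRT2 at 32.4 ± 21.9 CPM (1L). The cement gland and placode list had 12 of 33 models at 1 CPM and a median of 0.978 CPM, above 308 random lists. It was led by EYA1 at 103 ± 18.5 CPM (6S) and 63.4 ± 9.55 CPM on Scaffold52, and SIX4 at 86.8 ± 19.0 CPM (8S) and 86.1 ± 15.5 CPM (8L). The cement gland gene AGR2 had 97 and 3 reads in libraries 1 and 3 for its model on 6S.

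The Wnt and convergent extension list had 95 of 122 models at 1 CPM and a median of 26.3 CPM, above all 10000 random lists, and the FGF list had 45 of 57 and 22.5 CPM, with 1 random list higher. Fibronectin, FN1, reached 1714 ± 668 CPM (9_10S) and 1199 ± 463 CPM (9_10L), and PCDH8, the paraxial protocadherin, reached 1015 ± 23.4 CPM (2L) and 691 ± 66.0 CPM (7S). After CDX4, the FGF list was led by the receptor FGFR1 at 297 ± 71.1 CPM (3L) and ETV1 at 251 ± 85.1 CPM (6S). In the BMP list 54 of 66 models reached 1 CPM with a median of 10.5 CPM, above 9634 random lists. ID3 led it at 629 ± 88.5 CPM (2S) and 425 ± 8.43 CPM (2L), followed by CHRD and BMP7 at 95.9 ± 45.9 CPM (9_10L). Extracellular matrix genes took 1.40 ± 0.379% of reads, with 58 of 96 models at 1 CPM, a median of 6.26 CPM and fibrillin FBN2 at 1621 ± 556 CPM (1L) and 1119 ± 296 CPM (1S) beside FN1.

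**Figure D1:**
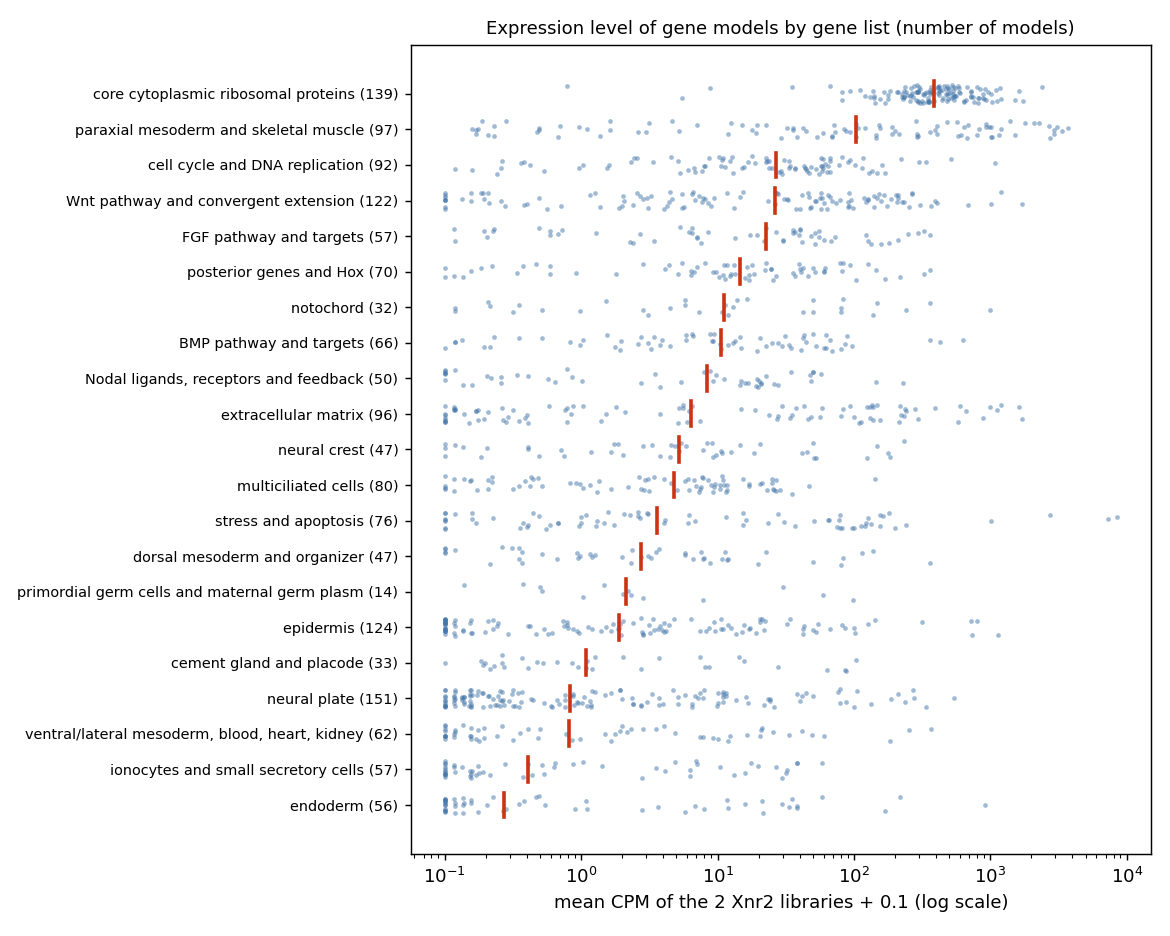
Mean CPM of the 2 Xnr2 libraries plus 0.1 (x axis, log scale) for each gene model of the 21 gene lists (rows, with the number of models); points are models and red bars are list medians. The paraxial mesoderm and skeletal muscle median of 102.8 CPM is exceeded only by that of the ribosomal proteins, and the endoderm median of 0.174 CPM is the lowest of the 21.

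The libraries were compared to see how far the level of a gene in xnr2 caps varied between pools of explants. Across all models the log2(CPM + 1) values had a Pearson correlation of 0.988 and a Spearman correlation of 0.982. A chi-square test over 18820 models gave 45.7 per degree of freedom, so that their counts differed by more than repeated sampling of 1 library gives. The labels list them as separate samples, and n = 2 rests on the labels. Of the 9565 models at 10 CPM or more, 88.0% differed by less than 1.5-fold. The exact binomial test of reads placed 9877 of 18820 models beyond counting error at an adjusted p under 0.05, and 738 of these were at least 2-fold higher in library 3 and 746 in library 1. The common biological coefficient of variation estimated by edgeR was 0.26. The log2 ratio of library 3 over library 1 also followed exon length across genes, with a Spearman correlation of 0.34 among the models at 10 CPM and 0.20 among all models with 10 reads. With the models at 10 CPM or more in 5 classes of length, the median ratio was -0.14 in the shortest (172 to 1514 bp) and 0.25 in the longest (4337 to 20100 bp).

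Notochord, matrix and multiciliated cell genes were higher in library 3. Of 28 notochord models with 10 reads, 24 were higher there, with a median log2 ratio of 0.69, where the central 95% of lists matched on level and length spanned -0.11 to 0.26. CHRD stood at 271 and 453 CPM in libraries 1 and 3 (5S), T at 58.7 and 108.5 CPM (5L) and the signalling protein SHH at 6.92 and 15.8 CPM (6L). Both FOXA2 models were among the 4 that were lower in library 3, at 14.0 and 9.85 CPM (5S) and 6.3 and 4.9 CPM (5L). Of 66 multiciliated models, 48 were higher in library 3 and 18 of them at least 2-fold, with a median of 0.51 against -0.13 to 0.18. The 9_10S model of TUBA1A stood at 80.4 and 206.5 CPM and the dynein DNAH9 at 3.36 and 9.92 CPM (9_10S) in libraries 1 and 3. Other models called TUBA1A had log2 ratios from -0.24 (9_10L, 51697281 to 51702065) to 1.94 (3L), with 0.17 on 2L. The symbol does not tell which Xenopus tubulin each of them is. The ciliary regulators RFX2, at 21.9 and 11.9 CPM (1L), and FOXJ1, at 5.45 and 3.42 CPM (9_10S), were lower in library 3, as was CEP152 at 19.1 and 11.6 CPM (3S). Matrix genes, whose models are long (median 4364 bp), were higher in 62 of 73 models, with a median of 0.43 against 0.04 to 0.25. The matrix and notochord lists share the models of PLOD1, PLOD2 and COL9A1, so their differences are not independent. The neural plate median of 0.21, against -0.12 to 0.13, also lay above its matched range, with 66 of 95 models higher. The Wnt list median of 0.20 exceeded its range of -0.00 to 0.18 by little. With copies of a symbol collapsed the Wnt list no longer lay outside, and the neural plate list did not when 100 reads were required. The medians of the organizer list (0.33) and of the cement gland and placode list (0.34) lay above their ranges as well, against their counts of large differences: 6 organizer models were at least 2-fold higher in library 3 and 9 lower, and 1 cement gland or placode model was higher and 8 lower. With copies collapsed, the difference of these lists from matched lists became -0.11 and -0.13.

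Epidermis genes and ribosomal protein genes were lower in library 3. Of 85 epidermis models 64 were lower there, 28 of them at least 2-fold beyond counting error while 2 were at least 2-fold higher. The median log2 ratio was -0.60, against -0.08 to 0.17 in matched lists. KRT19 had 172 and 31.8 CPM in libraries 1 and 3 (9_10S, 876177 to 879959), KRT12 had 27.7 and 2.36 CPM (9_10S, 1087214 to 1090663) and the secreted lectin ITLN1 had 30.5 and 0.718 CPM (7L). The share of reads in the list went the other way, 0.496% in library 1 and 0.534% in library 3. Among its most abundant models, KRT8 had 1043 and 1246 CPM (2L) and 666 and 928 CPM (2S) in libraries 1 and 3, and KRT18 had 751 and 719 CPM (2L) and 635 and 798 CPM (2S). Of 139 ribosomal protein models, which are short (median 828 bp), 136 were lower in library 3, with a median of -0.46 against -0.26 to -0.14, and the list took 7.61% and 5.61% of reads in libraries 1 and 3. RPL10A, the highest of them, had 2880 and 1940 CPM (2S). The medians of the cell cycle list (-0.09 against -0.05 to 0.15) and of the list of ventral and lateral mesoderm (-0.20 against -0.15 to 0.25) lay slightly below their ranges, the latter not when 100 reads were required. In each list 8 models were at least 2-fold lower in library 3 and 1 higher, of 87 and 37 models with 10 reads. In all, 11 of 21 lists lay outside the central 95%, where chance alone gives 1.05 of 21 if genes vary independently.

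The other 10 lists lay inside their matched ranges. The muscle list was among them, with a median of 0.04 and 50 models higher against 39 lower in library 3. In it, 3 models were at least 2-fold higher in library 3 and 4 lower, among them a model called TBX6 at 32.1 and 86.2 CPM in libraries 1 and 3 (1L), DMRT2 at 47.8 and 16.9 CPM (1L) and the glycolytic enzyme PGAM2 at 59.5 and 24.7 CPM (3L). A higher TBX6 model, on Scaffold22, had 103 and 139 CPM, and the symbol does not tell these genes apart. Also inside their ranges were the Nodal pathway (0.15), endoderm (-0.02), posterior and Hox (-0.03), BMP (-0.04), FGF (0.17), neural crest (0.09), ionocyte (0.02), stress (-0.11) and germ plasm (-0.02) lists. With copies collapsed and matching on length the BMP list lay just below the central 95% (percentile 2.48), and in lists matched on level alone the Nodal and FGF lists lay above it when 100 reads were required.

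**Figure D2:**
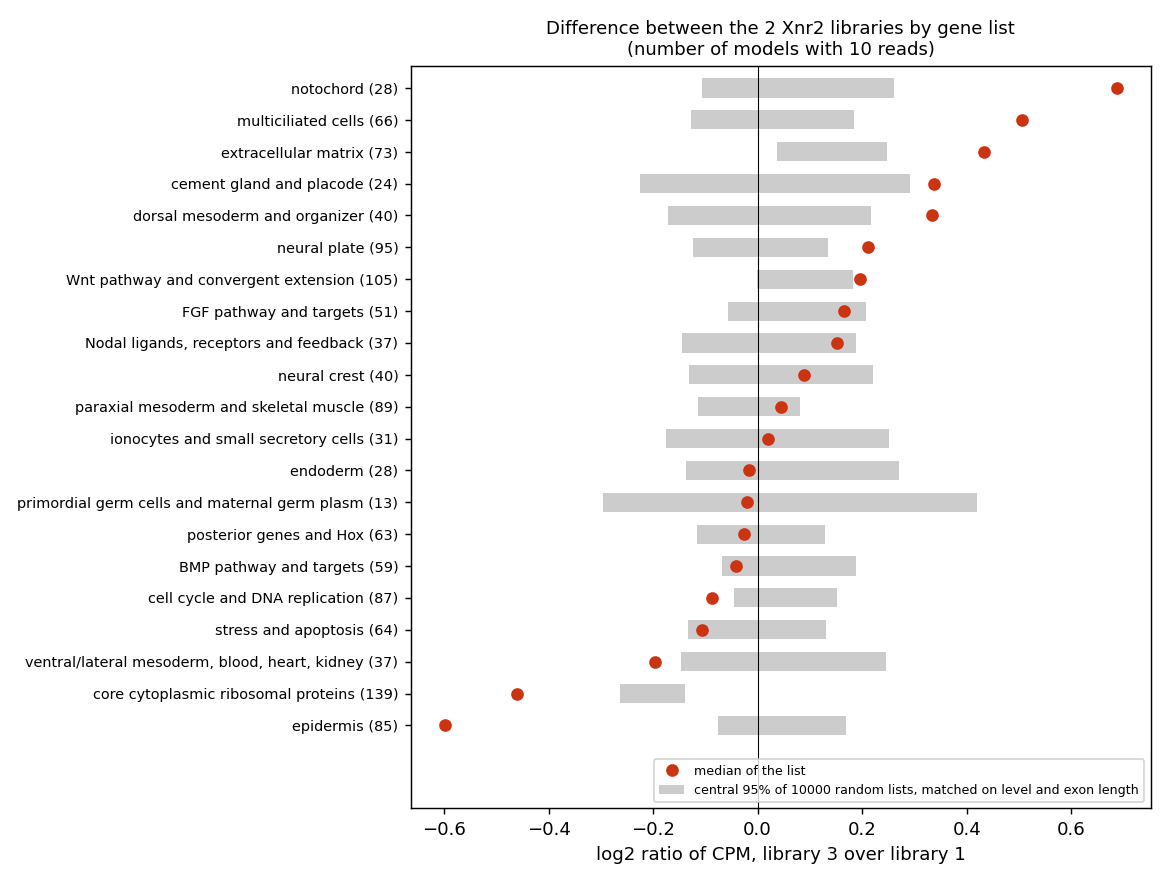
Median log2 ratio of CPM, library 3 over library 1 (x axis), for each gene list (rows, with the number of models with 10 reads); red points are list medians and grey bars the central 95% of 10000 random lists matched on level and exon length. Notochord (0.69) and multiciliated cell genes (0.51) lie to the right of their bars, and epidermis (-0.60) and ribosomal protein genes (-0.46) to the left.

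Single genes with large differences stood out from the rest. Of the models at 10 CPM or more, the 10 most in favour of library 3 were BAI1, BCO2, GLRX, HTT, ABCB5, LY9, FTH1, WWC3, GPRC5C and SEPT5. BAI1, an adhesion receptor, had 5 and 3472 reads in libraries 1 and 3 (6L, 150823329 to 150876406), BCO2, a carotenoid oxygenase, had 36 and 1782 (7L, 78312397 to 78345881), and the ferritin chain FTH1 had 15.8 and 81.1 CPM (7S, 80065451 to 80069219). Another BCO2 model on 7L had 580 and 569 reads. The 10 most in favour of library 1 were RCVRN, TSPAN8, LINGO1, SH3GL3, ITLN1, OTOG, FCGBP, ARID4B, KRT12 and GJB1. RCVRN, recoverin, had 3531 and 5 reads (9_10L, 42336205 to 42345266), where the neighbouring GSG1L had 123 and 19, while TSPAN8 had 2583 and 4 (3L) and OTOG, otogelin, had 528 and 22 (7L). For these examples the exact binomial test gave adjusted p-values of 7.14e-139 (OTOG) or smaller.

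**Figure D3:**
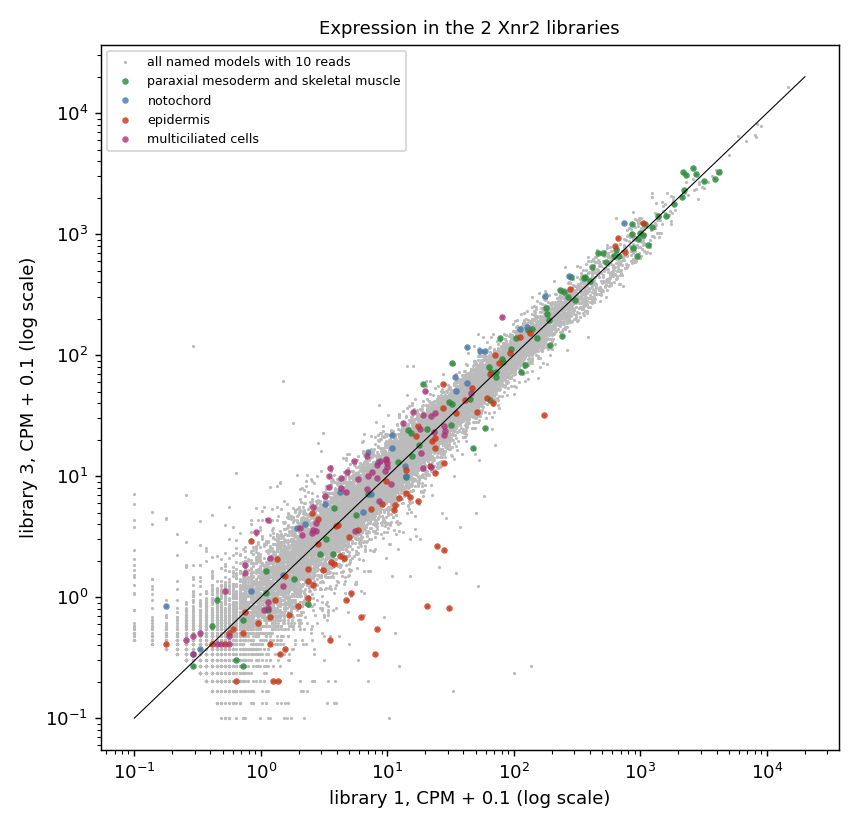
CPM plus 0.1 in library 1 (x axis) and library 3 (y axis), both on log scales, for all named models with 10 reads (grey) and for models of the muscle, notochord, epidermis and multiciliated lists (colours); the line marks equal values. Muscle models lie on both sides of the line (50 higher and 39 lower in library 3). KRT19 (172 and 31.8 CPM) and ITLN1 (30.5 and 0.718 CPM) lie below the line and the 9_10S model of TUBA1A (80.4 and 206.5 CPM) above it.

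X. laevis is an allotetraploid whose chromosomes form an L and an S set, and many genes keep 1 copy on each. Of 4934 such pairs with at least 20 reads, the L copy had the higher CPM per kb in 2759, which is 55.9% (exact 95% interval 54.5 to 57.3, 2-sided exact binomial test across pairs p = 9.62e-17). The median log2 ratio of L over S was 0.24. Levels of the copies were correlated across pairs (Spearman 0.72), and the L to S ratio was correlated between libraries (Spearman 0.96 across 3420 pairs with 100 reads per copy). Single ratios could still differ, as for AGPAT6, whose log2 ratio was 6.87 in library 1 and 4.47 in library 3. A difference of at least 2-fold in the same direction in both libraries was present in 2454 pairs, with L higher in 1461 and S higher in 993.

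The pairs with 100 reads per copy that leaned most to L were CKM, PFKP, FKBP10, ATP2A3, FMNL2, TMSB4X, ENO1, EEF1D, SMNDC1 and AGPAT6. CKM had 3362 ± 703 CPM from L and 3.04 ± 0.185 CPM from S, and the glycolytic enzyme ENO1 had 1343 ± 189 and 41.1 ± 8.11 CPM. Those that leaned most to S were RPS21, FBXL22, EIF5B, PLRG1, ARHGEF40, DDX23, GAPDH, AL138764.1, CHMP5 and ANPEP. The glycolytic enzyme GAPDH had 1602 ± 139 CPM from S and 40.9 ± 0.969 CPM from L, and FBXL22 had 1031 ± 69.2 and 16.4 ± 3.49 CPM. In 6 pairs the L copy exceeded 10 CPM while the S copy had 0 reads, with SH3BGRL highest at 161 ± 16.7 CPM. In 4 pairs the reverse held, with TXNDC17 highest at 74.6 ± 18.8 CPM. The exon lengths of these copies differ in the gene models (2263 and 657 bp for SH3BGRL), and reads common to both copies may be assigned to either, so single extreme ratios are uncertain.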

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

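No paired analysis was possible because the labels give 1 group. Alternatives on the authors' calls (adjusted p thresholds of 0.01 and 0.1, fold thresholds, read filter, collapsed copies, shared list members), on list medians of fold changes and on homeologs with called copies were not run, since no comparison between groups was analysed here. The tests of library differences, list levels and L to S ratios were chosen after the data had been seen, with their alternatives except the minimum of 10 reads per copy. The Pearson correlation of the libraries was 0.98377 with a pseudocount of 0.1 and 0.98133 with at least 10 reads. The number of models at 1 CPM or more was 15855 and lay between 15744 and 15859 with either library left out. The share of pairs with the L copy higher lay between 54.7% and 57.0% in all 6 alternatives, 55.8% to 55.9% with a library left out. With at least 100 reads fewer models were tested, and how far this accounts for a lower count was not tested. Models 2-fold apart then numbered 710, against 1484 with 10 reads. The side with more of them depended on the setting: 738 were higher in library 3 and 746 in library 1 with 10 reads, 396 and 314 with 100 reads, 655 and 840 under TMM, and 671 and 812 under DESeq2 scaling. Against random lists the organizer list turned from 0.30 above to -0.10937 with copies collapsed, and the cement gland and placode list from 0.30 to -0.12505 with copies collapsed and -0.037416 with no read filter; the causes were not tested. The epidermis level turned from the 0.59 to the 86.42 percentile with copies added up, and it stood at the 3.48 percentile without replicate 3. Of 21 list differences, 20 kept their side of the central 95% with matching on length, 21 with no matching, 20 with a pseudocount of 1, 18 with no read filter, 17 with 100 reads and 17 with copies collapsed; matching on length took the stress list inside. Depth limits statements on single low models: HHEX and GATA1, with 0 reads, lie under the floor of 3 reads, and GSC had at most 14 reads in a library.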

Other observations

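All patterns weighed here were noticed in the list medians and read counts first; the tests of epidermal share and of the NODAL span were chosen after their own values had been seen, the finer length test after the coarser one, and a minimum number of other copies, and the split of the chromosome block test, were added after those tests' values had been seen. Lists that served as checks on the tissue showed the following. Ribosomal proteins had 138 of 139 models at 1 CPM in both libraries with a median of 386 CPM, and cell cycle genes had 81 of 92 with a median of 26.6 CPM, both above all random lists. The cell cycle inhibitor CDKN1B led the latter at 1074 ± 75.5 CPM (7L), followed by WEE1 at 519 ± 183.5 CPM (4S) and the cyclin CCNA2 at 338 ± 30.4 CPM (1L). RPL10A (2410 ± 665 CPM, 2S) and RPL3 (1725 ± 214 CPM, 4L) led the former. Stress and apoptosis genes had 47 of 76 models at 1 CPM and a median of 3.48 CPM, with HSPA8 and then HSP90AB1 at 2735 ± 199 CPM (5S) at the top. Germ plasm genes, a check for tissue of the vegetal pole, had 9 of 14 models at 1 CPM and a median of 2.02 CPM. Their highest models were RTN3 at 98.6 ± 2.57 CPM (4L), DDX4 at 59.3 ± 8.90 CPM (1L) and TDRD7 at 30.0 ± 0.302 CPM (1L), of which RTN3 is widely expressed elsewhere.

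In lists picked after their values were seen, among pairs with 20 reads, the L copy was higher in 18 of 23 extracellular matrix pairs (median log2 ratio 1.91), 22 of 28 Wnt pairs (0.73), 13 of 15 FGF pairs (0.77) and 17 of 26 muscle pairs (0.77). It was higher in 28 of 53 ribosomal protein pairs (0.06) and in 4 of 15 pairs of the ventral and lateral mesoderm list (-0.31). Whether any list departs from the share over all pairs was not tested. Across the 3420 pairs with 100 reads per copy, the difference between the libraries in the L copy was correlated with that in the S copy (Spearman 0.50 across genes).

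Ribosomal protein genes were lower in library 3 than in library 1 in 136 of 139 models. A bias between the libraries in the recovery of short and long transcripts is a candidate explanation, since ratios rose with exon length across genes (Spearman 0.20 over all models with 10 reads and 0.34 at 10 CPM). Against lists matched on level and length the ribosomal median was still lower by 0.26 (-0.26), and against other genes in 20 finer steps of length the difference was -0.31, outside the central 95% both times, which argues against a length trend shared by all genes as the whole source. GC content and a difference in read length between the libraries were not tested. The labels name no difference between the libraries, so no biological explanation was tested. Notochord genes, tested against length and repeated copies in the same way, stayed above matched lists by 0.60 with length and 0.58 with copies collapsed, and were not weighed further.

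Epidermis genes were lower in library 3 while the list of multiciliated cell genes was higher. Gene length is unlikely to be the source, since the epidermis median lay 0.65 below (-0.65) lists matched on length, and repeated copies are unlikely too, since it lay at -0.48 with 1 value per symbol. A larger share of epidermal tissue of every kind in library 1 stays open. The multiciliated list lay 0.47 above its matched lists in library 3, but MCIDAS, CCNO, GMNC and CDC20B, which are specific to these cells, had at most 2 reads in a library. Of other regulators in the list, RFX2 and FOXJ1 were lower in library 3 and FOXN4 was higher. Whether the list measures that part of the epidermis here therefore cannot be told. The labels name no difference between the libraries that could be set against these explanations.

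A set of 9 models at 10 CPM or more differed at least 16-fold between the libraries, 2 higher in library 3 and 7 in library 1, among them BAI1 (5 and 3472 reads in libraries 1 and 3), RCVRN (3531 and 5), TSPAN8 (2583 and 4) and LINGO1 (849 and 2). A chromosome block that reaches the nearest models with 100 reads is argued against for the set by these 18 neighbours (median signed log2 ratio 0.11, bootstrap 95% interval -0.18 to 0.38). With RCVRN set apart after its neighbours were seen, none of the other 16 moved 2-fold the same way (0.018, -0.22 to 0.24). As RCVRN was set apart on these same ratios, the values of the other 16 are a description and add no separate support. For RCVRN a block stays open, since its neighbour GSG1L had 123 and 19 reads and both neighbours averaged 1.68, which rests on 2 models only. A cell program common to all copies of each gene cannot be told apart from a cause at the single locus, because only 2 other copies, of FCGBP and BCO2, had 100 reads. Their median of 0.25 (-0.20 to 0.70) lay under the bound of 1 set beforehand for excluding such a program, but that bound took no account of the 7 genes with no such copy.

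A NODAL model at 125408255 to 125412894 on 3L may be nodal2, the injected gene. Its span of 4640 bp differs by 0.77% from that of nodal2.L in a RefSeq table for assembly version 10.1 (4676 bp), where the closest other NODAL model differs by 18.6%, and its neighbour has the 2532 bp of nodal1.L. The model had 374 and 792 reads in libraries 1 and 3 (14.5 and 27.1 CPM). Gene names are not paired with paralogs in the deposited table, so this remains a hypothesis, and injected and endogenous RNA stay inseparable.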
